A study of Mus musculus with 6 samples.

How the data were processed

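RNA from sorted bone marrow monocytes of B6 mice was sequenced in 6 libraries, 3 from cells given GM-CSF and 3 control libraries. Per the labels' protocols, RNA was isolated with a Norgen kit and a DNase digest, poly(A) RNA was used and reads were paired. The deposited table holds raw read counts per gene symbol, with 1 column per sample, and each column was matched to its sample by title. The submitters' processing notes name Trim Galore 0.4.4, STAR 2.5.2a, HTSeq 0.6.1p1, edgeR and the build mm10, without stating the role of each tool. The version of edgeR that the authors used, the gene annotation behind the counts and the use of strand are not given in the sources used here. Reads from antisense or overlapping partners may therefore be mixed, and genes with near-identical copies lose reads that do not map uniquely.

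The table listed 24421 gene entries, of which 8273 had a count of 0 in every library. Entries that name no gene were left out of library sizes and tests. These were reads outside genes (7.82% to 9.72% of counted reads per library), ambiguous reads (1.44% to 1.53%) and reads without a unique position (18.0% to 19.6%), which left 69.4% to 71.3% in genes. Gene counts per library ran from 16643228 to 25232956, at which a count of 3, the limit that a count of 0 allows, equals 0.119 to 0.180 CPM. Between 13378 and 14253 genes had at least 1 read per library. For 24045 of the symbols, coordinates and gene types were taken from GENCODE M21 on GRCm38, the assembly that mm10 denotes.

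Groups were taken from the sample labels. Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM normalization (factors 0.987 to 1.02), filterByExpr with a minimum count of 10 and a minimum total of 15, and the two-sided quasi-likelihood F test (glmQLFit and glmQLFTest) with group as the only term. The filter left 11731 genes and removed 12690. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and a gene that passed is said to have changed. Log2 fold changes are GM-CSF against control and are given with SE, and CPM values are means with SD over 3 libraries, on the total of gene counts. The SE was obtained as the absolute log2 fold change divided by the square root of the F statistic. With few reads in a group it may be smaller than the error of counting alone. The common biological coefficient of variation was 0.119. Where a gene had 0 control reads, the fold is a lower bound against 3 reads over the group, and where it had 1 to 3, a ratio of counts per total with a 95% counting interval is given.

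The design, the 32 gene lists, the alternative settings and the rule for naming genes were fixed before the data were examined. The rule took the 6 largest rises and 6 largest falls among genes with a symbol other than a provisional, microRNA, small nucleolar or pseudogene name, an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between groups. It also took the 2 members of each response list with the largest absolute log2 fold change among those past the threshold with a mean log2 CPM of at least 1, the member of each list for other cells with the highest mean CPM, and Csf2ra, Csf2rb, Csf2rb2, Cish, Ly6c2, Ccr2, Cx3cr1, Cd14 and Tlr4 in any case. For families tested in the closing part it took the 2 members with the largest change. This gave 63 genes, and 95 others were chosen because 5 or fewer list members moved one way or after their values were seen; a few of these genes and 1 gene family are not reported here. Each list with at least 3 members tested was compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01. P-values were adjusted over the 30 lists tested. Camera was repeated with an estimated correlation, and fry, which does not compare a list with other genes, was run as well. The lists held 499 genes, 21 of them in more than 1 list. Summed CPM of the lists for other cells was compared by an exact two-sided permutation test, whose smallest p for 3 against 3 libraries is 0.1.

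The tests of genes, gene lists and gene families were recomputed with size factors of the DESeq2 kind, with library size alone and with upper quartile scaling. Others had no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, a robust prior or a replicate block. Further ones left out each library in turn, or removed the 10 most abundant genes and the haemoglobin genes. The haemoglobin genes had 0 reads, so only the removal of the abundant genes mattered. The remaining alternatives used limma-voom or the DESeq2 1.42.0 Wald test. Summed CPM was recomputed with TMM-scaled CPM alone. A correction for transcript GC content (a loess trend per library, span 0.5) and families of genes sharing a symbol prefix, with at least 10 members, were added after seeing the data. The procedure was tested on 1 set of simulated counts for GM-CSF against control. In it, 200 of 11731 genes were changed and a further set of 20 was raised 2-fold, with dispersions from the fitted trend. It recovered 65.7% of 67 genes changed 1.5-fold, 83.6% of 67 changed 2-fold and 98.5% of 66 changed 4-fold. Of its calls, 3.70% were false. Far more genes, 64.0%, were called in the data, so these shares may not carry over to them. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.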

Results

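Messenger RNA was sequenced from monocytes, circulating phagocytes that are made in the bone marrow, sorted from the marrow of B6 mice. The comparison asks which genes respond when such cells meet granulocyte-macrophage colony-stimulating factor (GM-CSF), a cytokine that acts on myeloid cells, in a study concerned with lipopolysaccharide (LPS) and allergic inflammation. There were 3 GM-CSF libraries, from cells given 5 ng of the cytokine (no volume is stated) for 3 h, and 3 control libraries. One label calls the control cells freshly isolated, while others describe 3 h in medium with or without the cytokine, so the labels leave open whether the control cells were cultured; if they were not, time in culture differs between the groups along with GM-CSF. Nothing in the labels says that replicates came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical. The GM-CSF libraries held 16780355, 16643228 and 21468929 reads assigned to genes, and the control libraries 23994546, 25232956 and 20782467. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.992 for each pair of control libraries and 0.991 for GM-CSF replicates 1 and 2. GM-CSF replicate 3 correlated at 0.980 and 0.983 with the other GM-CSF libraries, and pairs from different groups at 0.883 to 0.897.

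GM-CSF libraries had far higher levels of Cish, a feedback inhibitor of cytokine receptor signalling, which went from 1.46 ± 0.739 to 2046 ± 250.3 CPM (SD, n = 3 per group; log2 fold change 10.43 ± 0.24, SE; edgeR adjusted p = 1.24e-10). Spint1, a membrane-bound inhibitor of serine proteases, rose to 556 ± 106 CPM from 5 control reads, all of them in control replicate 2. Its fitted log2 fold change was 12.82 ± 0.33, an SE that may be too small with so few control reads. Without control replicate 2, 0 control reads were left and the fitted value was 16.44. The actin-associated gene Synpo and the serotonin receptor gene Htr7 had 0 control reads and were at least 787-fold and at least 423-fold higher, taking 3 reads over the control group as the limit that a count of 0 allows. Among genes with a mean log2 CPM of at least 3, a limit that leaves out some larger falls at lower levels, the largest falls were in Kcne3, a potassium channel subunit (23.6 ± 2.76 to 0.324 ± 0.128 CPM; log2 fold change -6.14 ± 0.24), and S1pr5, a receptor for sphingosine-1-phosphate (-5.74 ± 0.23). In all, 7511 of 11731 tested genes (64.0%) changed at an adjusted p under 0.05, 3851 of them higher and 3660 lower. Of these, 1394 were at least 2-fold higher and 1482 at least 2-fold lower.

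The other genes with the largest rises by the rule used here were Cxcl3, a neutrophil-attracting chemokine, and Emp1, which encodes a membrane protein. Emp1 rose from 0.536 ± 0.221 to 465 ± 91.8 CPM (log2 fold change 9.77 ± 0.24). Cxcl3 had 3 control reads and a ratio of 1009 with a 95% counting interval of 345 to 4898. Other large falls were in BC147527 (-4.99 ± 0.16), the lysophosphatidic acid receptor Lpar5 (-4.12 ± 0.18) and the lysosomal sulfatase Sgsh (-4.12 ± 0.15). On GRCm38, Cish lies on chromosome 9 at 107296026 to 107302784, Spint1 on chromosome 2 at 119237362 to 119249527, Kcne3 on chromosome 7 at 100176502 to 100184869 and S1pr5 on chromosome 9 at 21242912 to 21248443. All 4 are annotated as protein-coding. Intervals and limits cover counting error only. Of the 63 genes chosen by a fixed rule, 59 passed the threshold. In 58 of these no control library overlapped a GM-CSF library, and Hspa1b overlapped. Both counts were largely fixed in advance. The rule took most genes from those past the threshold, and the largest changes only from genes without overlap. Of all 11731 tested genes, 7511 (64.0%) passed and 8156 (69.5%) had no overlap. Further members of the gene lists were chosen where 5 or fewer moved one way, or after their values were seen.

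**Figure D1:**
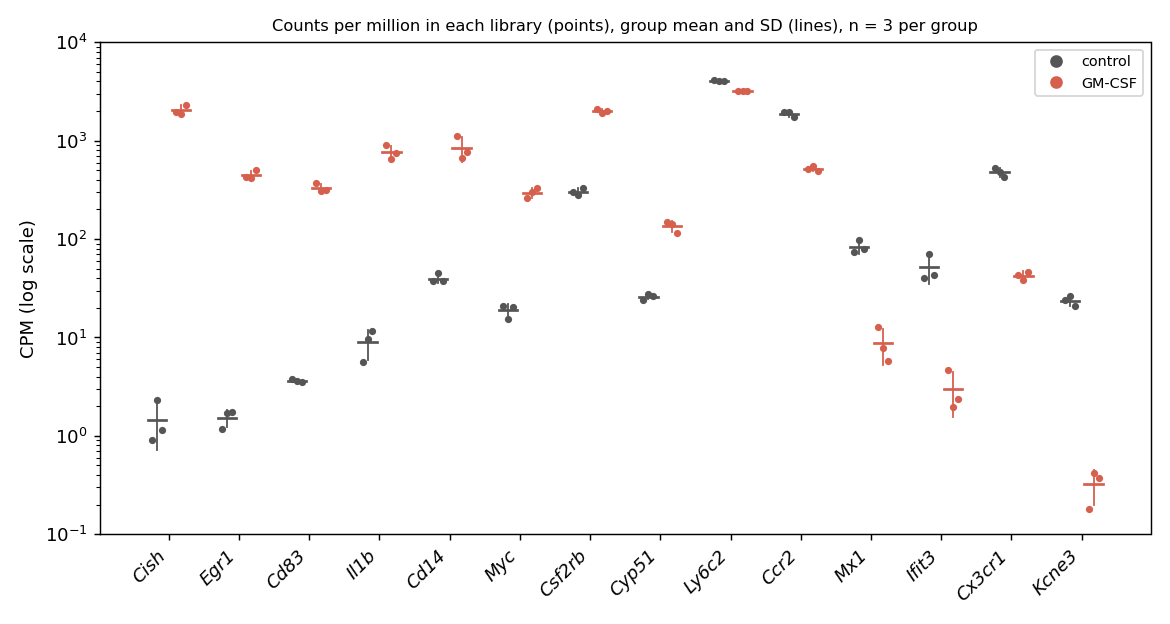
CPM on a log scale for 14 genes in each of the 6 libraries, with points for libraries and lines for the mean and SD of the 3 libraries of each group. Cish, Egr1, Cd83, Il1b, Cd14, Myc, Csf2rb and Cyp51 were higher in every GM-CSF library than in any control library, and Ly6c2, Ccr2, Mx1, Ifit3, Cx3cr1 and Kcne3 were lower.

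Most STAT5 targets and cytokine feedback genes rose. Of 19 tested, 16 rose, 1 fell and 2 did not pass the test (median log2 fold change 2.59). Besides Cish, Socs2 went from 3 control reads to 28.3 ± 1.97 CPM, a ratio of 661 (95% counting interval 226 to 3207), Socs3 rose by 7.27 on the log2 scale and the cytokine gene Osm by 6.73. The fitted log2 fold change of Socs2, 9.18, was 9.99 without control replicate 1 and 8.59 without control replicate 2. The member that fell was Bcl6 (-0.89 ± 0.11), a transcriptional repressor. Of 25 immediate early and MAPK feedback genes, 21 rose and 3 fell (median 1.35). The zinc finger transcription factors Egr2 and Egr1 went from 0.743 ± 0.231 and 1.53 ± 0.319 CPM to 447 ± 13.3 and 448 ± 48.0 CPM. The members that fell were Fos (-1.35), Klf2 (-1.37) and the ERK phosphatase gene Dusp6 (-2.12). Camera, which compares a list with all other genes, gave adjusted p = 1.67e-19 for the STAT5 list and 5.60e-13 for the immediate early list with its preset correlation. Both lists had adjusted p = 0.0573 with an estimated correlation.

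Of the 2 chains of the GM-CSF receptor, the beta chain rose while the alpha chain did not pass the test. Csf2rb, the signalling chain shared with the IL-3 and IL-5 receptors, went from 304 ± 24.5 to 2000 ± 88.9 CPM (log2 fold change 2.73 ± 0.09), and its neighbouring paralog Csf2rb2, whose product serves the IL-3 receptor, rose by 2.94 ± 0.11. Csf2rb and Csf2rb2 lie next to each other on chromosome 15, at 78325752 to 78353847 and 78282507 to 78305721, and reads of their shared sequence may be split between them or left out. Csf2ra was at 482 ± 48.5 CPM in control and 508 ± 54.4 CPM in GM-CSF libraries (log2 fold change 0.08, adjusted p = 0.449), its sign turned with upper quartile scaling (-0.03), and with the GC correction it was called (0.21). In the receptor list of 9 genes, Jak2 (2.65) also rose and Stat5a (-0.40), Stat5b (-0.55) and the G-CSF receptor Csf3r (-1.45) fell. The list was not called by camera (adjusted p = 0.0653), though it passed without control replicate 2 (0.0490) and without GM-CSF replicate 1 (0.0295).

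Most inflammatory cytokine and chemokine genes rose. Of 24 NF-kB targets and inflammatory cytokines, 22 rose and none fell (median 1.53), led by the activation marker Cd83 (3.64 ± 0.142 to 332 ± 35.7 CPM) and by Il1b, which encodes interleukin 1 beta (8.94 ± 3.05 to 769 ± 124 CPM); Il6 rose by 5.96 and Tnf by 2.23 on the log2 scale. Adjusted over the list alone, 1 member was lower as well, Nfkbiz (-0.27, adjusted p = 0.0511 over all genes). Of 17 chemokines, 12 rose and 4 fell (median 3.25). Ccl22 had 0 control reads and was at least 125-fold higher, and Ccl17 had 3 and a ratio of 410 (95% counting interval 140.0 to 1993); both proteins bind CCR4. Ccl7 had 3 control reads and a ratio of 927 (317 to 4500). The fitted log2 fold change of Ccl17 moved from 8.50 to 9.38 without control replicate 3 and that of Ccl7 from 9.71 to 10.48 without control replicate 2. Ccl24 and Ccl2 rose by 7.78 and 5.05 on the log2 scale. The 4 that fell were Ccl9 (-0.72), Ccl6 (-1.02), Ccl5 (-1.34) and Cxcl9 (-2.13). The Ccl5 call ended without control replicate 3 (-1.19) and with DESeq2 (-1.36), and the Cxcl9 call without control replicate 1 (-1.94); Cxcl9 was at -2.86 without GM-CSF replicate 3. Camera adjusted p was 2.47e-15 for the NF-kB list and 5.54e-09 for chemokines, and adjusted p = 0.0810 and 0.121 with an estimated correlation.

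Interferon-stimulated genes fell without exception among the members tested. All 28 were lower (median -2.13; camera adjusted p = 2.17e-18, adjusted p = 0.163 with an estimated correlation). Ifit3 went from 51.6 ± 16.6 to 3.00 ± 1.44 CPM and the antiviral GTPase gene Mx1 from 84.0 ± 12.8 to 8.76 ± 3.57 CPM. Irf7 fell by 2.59 and Isg15 by 1.86 on the log2 scale. Cxcl10, a chemokine gene that interferons also induce and that was counted with the chemokines, rose by 2.95.

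Genes for sensing LPS and other microbial ligands went both ways. Of 21 tested, 10 rose and 8 fell. The LPS co-receptor Cd14 rose from 39.7 ± 4.33 to 851 ± 244 CPM, Tlr4 from 28.9 ± 5.15 to 181 ± 32.3 CPM and Tlr2 by 3.04 on the log2 scale, while Ly96, whose product binds LPS together with TLR4, fell by 1.25. The endosomal receptor genes Tlr9 (-3.28 ± 0.29) and Tlr7 (-2.34) and the TLR4 inhibitor gene Cd180 (-2.33) fell. The list's median (-0.01) and mean (0.25) differed in sign, and camera did not call it (adjusted p = 0.204). Of 6 Fc receptor genes, Fcgr2b, which encodes the inhibitory IgG receptor, rose from 207 ± 7.19 to 1234 ± 43.3 CPM and Fcgr3 from 509 ± 54.1 to 1525 ± 90.5 CPM, whereas Fcer1g (-0.46), Fcgr1 (-0.86) and Fcgr4 (15.2 ± 2.55 to 5.31 ± 0.737 CPM) fell. This list's median (-0.12) also differed in sign from its mean (0.26) and its camera direction, and it was not called (adjusted p = 0.252).

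Antigen presentation and co-stimulation genes went both ways. Of 18 tested, 8 rose and 5 fell (median 0.02, or -0.10 with upper quartile scaling). The PD-1 ligand genes Pdcd1lg2 and Cd274 rose, the first from 5 control reads to 767 GM-CSF reads (log2 fold change 7.51 ± 0.35, and 8.16 without control replicate 1) and the second from 4.24 ± 1.74 to 128 ± 3.39 CPM. With so few control reads, the SE of Pdcd1lg2 may be too small. Cd80 and Cd86 rose by 4.46 and 2.15 on the log2 scale. The members that fell were H2-K1 (-0.25), H2-D1 (-0.26), B2m (-0.44), H2-Aa (-0.48) and the peptide transporter Tap1 (-1.43). The call of H2-Aa ended without any single one of control replicates 1, 2 and 3 or GM-CSF replicate 2 (-0.49 to -0.47), and with the robust prior (-0.48). Its value was -0.72 without GM-CSF replicate 1 and -0.27 without GM-CSF replicate 3. The calls of H2-K1 and H2-D1 ended with the GC correction (-0.18 and -0.15). Camera called the list higher (adjusted p = 0.0119; adjusted p = 0.449 with an estimated correlation and 0.329 with limma-voom).

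Most genes of the lists for a dendritic cell fate of monocytes and for alternative activation rose. Of 13 in the dendritic cell list, 10 rose, led by the transcription factor Irf4 (14.3 ± 1.87 to 135 ± 6.94 CPM) and the lectin gene Cd209a (39.9 ± 15.1 to 173 ± 23.1 CPM), and only Dpp4 fell (-0.68; not called without control replicate 2, -0.59). The camera adjusted p was 0.00823, and adjusted p = 0.131 with an estimated correlation. Of 16 alternative activation and allergic inflammation genes, 10 rose, Ccl22, Ccl17, Ccl24 and Arg1 (5.19) among them, and 4 fell, namely Chil3 (-0.97), Il13ra1 (-1.31), Alox5ap (-1.38) and Cd163 (-2.12). That list had a median of 1.44 and a camera adjusted p of 6.52e-04, with adjusted p = 0.0995 with an estimated correlation and 0.0711 with limma-voom.

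Markers of monocyte subsets mostly fell. Of 17 classical monocyte genes, 12 fell and 2 rose (median -0.86). Lyz2, the lysozyme gene, went from 56025 ± 4548 to 21394 ± 1053 CPM, Lcn2 from 972 ± 185 to 251 ± 42.8 CPM and the chemokine receptor gene Ccr2 from 1877 ± 129.9 to 521 ± 29.1 CPM, while Ly6c2, a marker of classical monocytes, fell by 0.34 ± 0.07 on the log2 scale. The proteoglycan gene Vcan rose (2.91 ± 0.19). Camera adjusted p was 4.58e-04, and adjusted p = 0.306 with an estimated correlation. In the same libraries the neutrophil granule list fell from a sum of 24929 ± 4602 to 10781 ± 1330 CPM. Some genes of the classical monocyte list, such as Lcn2, may also come from neutrophil precursors. Whether their fall took place within monocytes was not tested.

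Of 18 non-classical monocyte genes, 12 fell and 5 rose (median -1.25). Cx3cr1, the fractalkine receptor that is high on non-classical monocytes, went from 481 ± 48.8 to 42.7 ± 4.22 CPM, and Ace (-3.14) and Treml4 (-1.98) fell; Ace was at -3.98 without GM-CSF replicate 1. The lipid-handling genes Fabp4 (4.57 ± 0.27) and Cd36 (4.36 ± 0.21) rose, as did Nr4a1 (2.03), Pparg (1.56) and Cebpb (3.46). Cebpb rested largely on GM-CSF replicate 3, at 3789 CPM beside 575 and 925 CPM in the other GM-CSF libraries, and was at 2.23 without it. Camera gave adjusted p = 0.0473, which was lost without GM-CSF replicate 2 (0.0696) or 3 (0.0506), with limma-voom (0.0680), with upper quartile scaling (0.0637), without the most abundant genes (0.0521), with the GC correction (0.0730) and, at adjusted p = 0.238, with an estimated correlation.

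Chemokine receptor and trafficking genes moved in both directions, 7 of 18 higher and 8 lower (8 and 8 adjusted over the list alone; camera adjusted p = 0.453). Cx3cr1 and Ccr2, given above, were among those that fell.

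**Figure D2:**
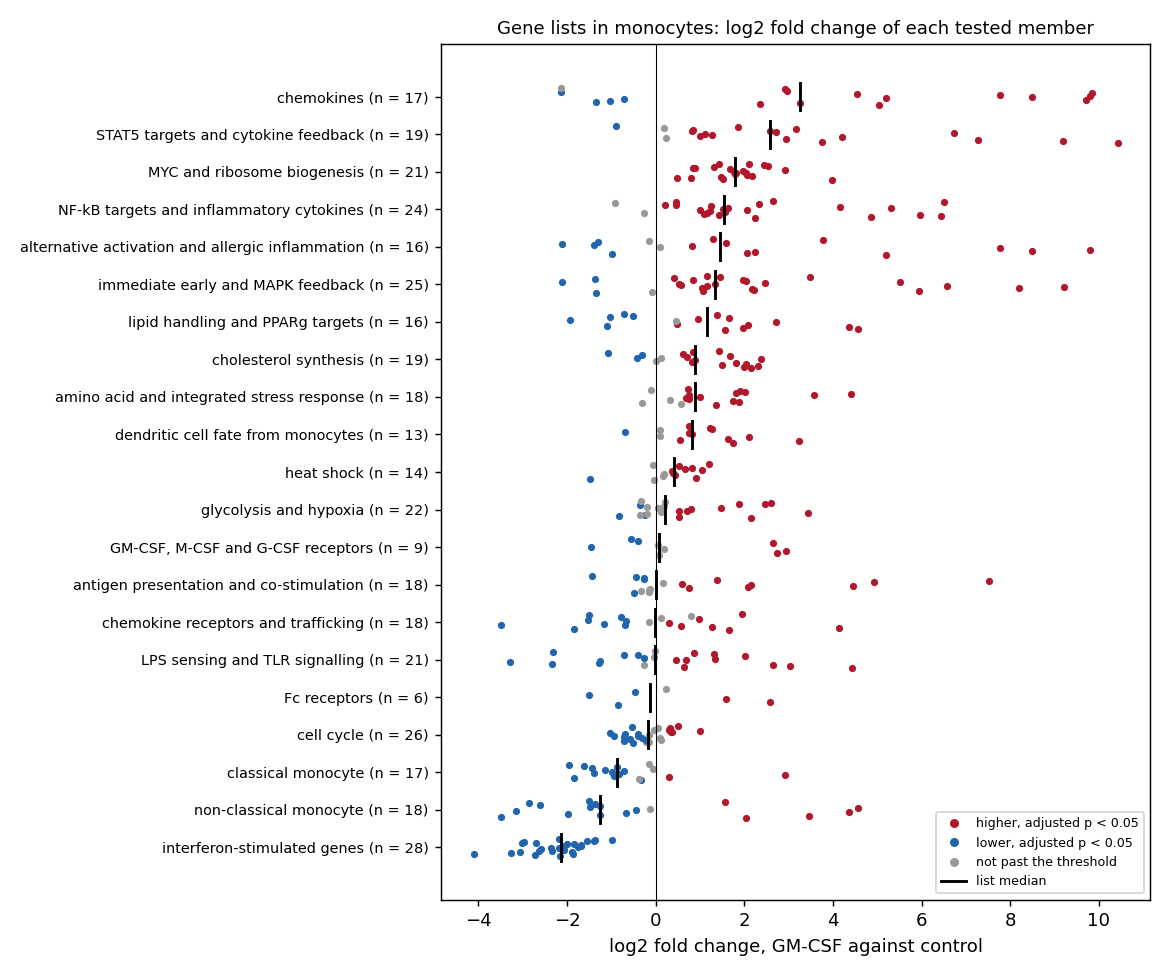
Log2 fold change of each tested member of the 21 response lists, GM-CSF against control, 1 point per gene, with a black line at the list median. Interferon-stimulated genes all lie to the left of 0, with a median of -2.13, and the chemokines have the highest median, 3.25; Cish, in the STAT5 list, lies farthest to the right, and points of genes with 0 to 3 control reads, such as Ccl22, are fitted values.

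Most members of the MYC and ribosome biogenesis, amino acid and integrated stress response, and cholesterol synthesis lists rose. All 21 MYC and ribosome biogenesis genes were higher (median 1.80), with Myc itself going from 18.8 ± 2.91 to 297 ± 36.1 CPM and the nucleolar gene Gnl3 from 12.4 ± 1.44 to 92.2 ± 8.61 CPM. Of 18 amino acid and integrated stress response genes, 14 rose and none fell (median 0.89); the amino acid transporters Slc7a5 and Slc7a11 rose by 4.40 ± 0.12 and 3.56 ± 0.20 on the log2 scale. Of 19 cholesterol synthesis genes, 14 rose (median 0.89), Cyp51 by 2.38 ± 0.11 and Sqle by 2.30 ± 0.12, while Nsdhl (-0.32), Dhcr7 (-0.42) and Mvk (-1.07) fell. The Nsdhl call ended without control replicate 1 (-0.23) or 2 (-0.33) or GM-CSF replicate 1 (-0.27) or 2 (-0.33), and the Dhcr7 call without control replicate 2 (-0.34) or 3 (-0.43) or GM-CSF replicate 1 (-0.33) or 2 (-0.38). Camera adjusted p was 1.67e-19, 7.30e-06 and 3.30e-07 for these 3 lists, and adjusted p = 0.124, 0.295 and 0.0573 with an estimated correlation.

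Glycolysis and lipid genes were less uniform. Of 22 glycolysis and hypoxia genes, 10 rose and 3 fell (median 0.21; camera adjusted p = 0.0168, adjusted p = 0.532 with an estimated correlation and 0.0936 with limma-voom). Pfkp, a phosphofructokinase, rose from 178 to 1917 CPM (log2 fold change 3.44 ± 0.09) and the oxygen sensor gene Egln3 from 6.42 ± 0.569 to 38.8 ± 18.6 CPM, and the hexokinase genes Hk1 (-0.82) and Hk2 (-0.25) and Gpi1 (-0.35) fell. The Hk2 call ended without control replicate 1, 2 or 3 or GM-CSF replicate 2 or 3 (-0.28 to -0.18), and with the GC correction (-0.22). Of 16 lipid handling and PPARg targets, 10 rose and 5 fell, the latter being Soat1 (-0.52), Scd2 (-0.72), Acsl1 (-1.02), Plin2 (-1.09) and Cpt1a (-1.93); camera did not call the list (adjusted p = 0.156). Of 14 heat shock genes, 9 rose, among them the endoplasmic reticulum chaperone gene Hspa5 (1.21 ± 0.08), and Hspa1b fell (-1.47 ± 0.47). Hspa1b stood at 136 CPM in control replicate 1 and at 33.0 and 40.6 CPM in the other controls, so that without control replicate 1 its log2 fold change was -0.53 and not called, and without GM-CSF replicate 2 it was -1.25 and not called. The Hspa1b call also ended with the robust prior (-1.47), limma-voom (-1.22) and DESeq2 (-1.48), and its reads may be shared with the near-identical Hspa1a. The heat shock list had a camera adjusted p of 0.0969, and 0.0205 without control replicate 1. Of 26 cell cycle genes, 7 rose and 12 fell, with the replication helicase gene Mcm4 at 1.01 ± 0.07 and the mitotic gene Cenpf at -1.04 ± 0.13 (camera adjusted p = 0.318).

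Markers of other marrow cells were checked in the same libraries. Of 10 neutrophil and granule genes, 7 fell (median -1.04; camera adjusted p = 0.0214; adjusted p = 0.532 with an estimated correlation, and 0.0807 without the most abundant genes, which include members of this list). S100a8 went from 8137 ± 1537 to 3584 ± 471 CPM, Ngp fell by 1.25 and Camp by 1.43 on the log2 scale, and BC100530 rose (4.73 ± 1.11) on 16.1 CPM in GM-CSF replicate 3 against about 1.13 and 1.08 CPM in the other GM-CSF libraries (2.25 without replicate 3; not called with the robust prior, 4.73). The list's summed CPM gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Granulocyte-monocyte progenitor genes did not move together: summed CPM was 8189 ± 1393 in control and 8920 ± 1083 in GM-CSF libraries (exact permutation p = 0.5). Mpo was at 0.18 ± 0.13 (adjusted p = 0.263; called with the GC correction, 0.29), Cd34 (0.86), Ms4a3 (0.37) and Ctsg (0.31) rose, and Kit (-0.54) and Prss57 (-0.65) fell (camera adjusted p = 0.970). The Ctsg call ended without control replicate 1 (0.23) or 2 (0.28) or GM-CSF replicate 2 (0.28) or with upper quartile scaling (0.19), the Ms4a3 call with the GC correction (0.16), and the Kit call without control replicate 2 (-0.48) or 3 (-0.41).

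Lymphoid, erythroid and platelet markers were low among the genes that could be measured. Tests covered 8 of 10 B cell, 3 of 11 T and NK cell and 5 of 12 erythroid genes. The haemoglobin genes had 0 reads in every library, so the erythroid sum rests on other genes and cannot show how many red cells were present. Summed CPM in control and GM-CSF libraries was 72.5 ± 5.00 and 39.7 ± 4.95 for B cell genes, 4.14 ± 0.469 and 2.89 ± 0.446 for T and NK cell genes and 11.8 ± 0.247 and 5.10 ± 2.82 for erythroid genes, each with an exact permutation p of 0.1. In the B cell list Cd79b (-1.27 ± 0.14), Vpreb1 (-1.46), Vpreb3 (-1.60) and Igll1 (-2.47) fell, Il2rb was the T and NK cell gene that fell (-2.18 ± 0.46), and Car2 (-1.10 ± 0.22), Alas2 (-1.84) and Klf1 (-2.02) fell among erythroid genes. Megakaryocyte and platelet genes summed to 29.2 CPM in control replicate 3 and to 2.12 to 3.34 CPM in every other library; Pf4 was at 11.3 CPM there, and its log2 fold change of -2.14 (adjusted p = 0.159) became 2.51 without that library. The falls of Gp9 (-1.83) and Itga2b (-1.96) ended without control replicate 3 (-0.79 and -0.76), GM-CSF replicate 1 (-1.78 and -1.93), 2 (-1.89 and -2.02) or 3 (-1.81 and -1.93) and with limma-voom (-1.37 and -1.42), and no member passed when adjusted over the list alone. The Vpreb1 call ended without control replicate 2 (-1.39) or 3 (-1.25) or GM-CSF replicate 2 (-1.26), and the Klf1 call without control replicate 1 (-1.99), 2 (-2.15) or 3 (-1.90) or GM-CSF replicate 2 (-2.20). Without GM-CSF replicate 1, Klf1 was at -2.80 and Igll1 at -3.31, and without GM-CSF replicate 3 Klf1 was at -1.34.

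Of 9 conventional and plasmacytoid dendritic cell genes, Ly6d (-0.54), Tcf4 (-0.95 ± 0.11), Ccr9 (-1.41), Flt3 (-1.57) and Siglech (-1.77) fell and Runx2 (1.30) and Zbtb46 (1.63) rose; adjusted over the list alone, 3 were higher. Their summed CPM was 73.1 ± 0.939 in control and 54.7 ± 0.782 in GM-CSF libraries (exact permutation p = 0.1). The Zbtb46 call ended without control replicate 1 (1.39) or 3 (1.38) or GM-CSF replicate 1 (1.26) or 2 (1.47), or with upper quartile scaling (1.52), DESeq2 (1.68) or limma-voom, and its value was 2.37 without control replicate 2. The Ccr9 call ended without control replicate 1 (-1.24), 2 (-1.45) or 3 (-1.56) or GM-CSF replicate 1 (-0.98) or 2 (-1.42), and it was at -2.09 without GM-CSF replicate 3. The Siglech call ended without GM-CSF replicate 2 (-1.64), and its value was -2.84 without replicate 3. Among basophil, mast cell and eosinophil genes, Gata2 (4.48 ± 0.37) and Ms4a2 (1.04; not called without control replicate 1, 1.04, or 3, 0.89, or GM-CSF replicate 2, 0.90) rose, whereas Siglecf was at -0.35 (adjusted p = 0.0784, called without control replicate 1, -0.49, and with upper quartile scaling, -0.47); the list's median (-0.31) was opposite in sign to its mean (0.91). Its summed CPM was 25.4 ± 7.39 and 32.0 ± 6.69 (exact permutation p = 0.4).

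Mature macrophage genes summed to 522 ± 16.7 CPM in control and 575 ± 149 CPM in GM-CSF libraries (exact permutation p = 0.7). Adgre1, the gene of the macrophage marker F4/80, rose by 0.80 ± 0.14 and Mertk by 2.17, Slc40a1 fell by 1.45, and the list's median (-0.15) and mean (0.02) differed in sign. Stroma and endothelium genes summed to 15.7 ± 1.63 and 11.3 ± 1.64 CPM (exact permutation p = 0.1), and Pecam1 fell (-0.41 ± 0.15), a call that ended without control replicate 2 (-0.32) or 3 (-0.43) or GM-CSF replicate 3 (-0.28). Megakaryocyte sums gave an exact permutation p of 1. Camera called none of the B cell, T and NK cell, erythroid, dendritic cell, basophil, megakaryocyte and mature macrophage lists (adjusted p = 0.183, 0.636, 0.3001, 0.499, 0.612, 0.636 and 0.782). Only 2 of the 9 stroma and endothelium genes were tested, too few for camera, and the table held 0 of 13 mitochondrially encoded genes, so their share of reads was not analysed here.

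Over all 30 lists tested, camera with its preset correlation called 15, of which 11 were higher and 4 lower. With a correlation estimated from these libraries none was called, although 9 had an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, called 25. For each of the 15 lists, the estimated correlation gave the largest adjusted p of 19 alternatives; the lowest lay between 7.57e-27, for the STAT5 and MYC lists, and 0.00280, for glycolysis. Adjusted over the list alone, the numbers of higher and lower members were the same as over all genes in 26 of the 30 lists. The other 4 are the NF-kB, chemokine receptor, dendritic cell marker and platelet lists, with the values given above.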

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

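The GC correction and the families of genes were chosen after seeing the data; all other alternatives were fixed earlier. The number of changed genes stayed within 1.5 times of 7511 in every alternative, from 6739 without control replicate 3 to 7739 without GM-CSF replicate 3. Without GM-CSF replicate 3, 7145 of the genes were shared with the full set, 366 were lost, 594 were gained and 0 changed sign. Upper quartile scaling moved the median of all genes by -0.12 and gave 3257 higher and 4318 lower genes, or 43.0% higher against 51.3%. Of the 158 chosen genes 153 were called, and 129 of these kept their call in every alternative. Summed levels of other cells, Lars2, Rn45s and Mir6236 moved by less than the spread with TMM-scaled CPM. Same-numbered samples did not deviate together (correlations 0.07, 0.01 and 0.00, and 2 of 6 samples correlated best with their own number), so numbers were not taken as pairs; the replicate block gave 7493 genes. The filter left out 12690 genes, of which 8273 had a count of 0 in every library; with no filter 16148 genes were tested and 7673 changed. For T and NK cell, erythroid and megakaryocyte lists, 1 alternative left too few members and gave no value.

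The sign of Csf2ra turned with upper quartile scaling (-0.034), and that of Pf4 with limma-voom (0.33) and between -2.72 and 2.51 when single libraries were left out, the highest without control replicate 3. The progenitor list, near 0 throughout, turned direction with upper quartile scaling (adjusted p = 0.997), the replicate block (0.970), removal of abundant genes (0.987) and DESeq2 (0.985), and also without control replicate 1 (0.775) or 2 (0.945) or GM-CSF replicate 2 (0.984) or 3 (0.862); with single libraries left out its adjusted p ran from 0.651 to 0.984. The megakaryocyte list had 0.478 to 0.841 and turned without control replicate 3. The cause was not tested for these.

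With an estimated correlation no list was called. Adjusted p was 0.0573 for the STAT5, immediate early and cholesterol lists, 0.0810 for NF-kB, 0.0995 for alternative activation, 0.121 for chemokines, 0.124 for MYC, 0.131 for dendritic cell fate and 0.163 for interferon-stimulated genes. It was 0.238 for non-classical and 0.306 for classical monocytes, 0.295 for amino acids, 0.449 for antigen presentation and 0.532 for both glycolysis and neutrophil genes. The non-classical list was also lost with upper quartile scaling (0.0637), without abundant genes (0.0521), with limma-voom (0.0680) and with the GC correction (0.0730), and ranged from 0.0194 to 0.0696 with single libraries left out. The neutrophil list was lost without abundant genes (0.0807), a setting that removes its members S100a8 and S100a9. Limma-voom also lost antigen presentation (0.329), alternative activation (0.0711) and glycolysis (0.0936). The cause was not tested, and the removal of S100a8 and S100a9 was not separated from that of the other abundant genes.

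The receptor list passed with no filter (0.0190), DESeq2 (0.0176), the GC correction (0.0412) and fry (4.23e-04), and ranged from 0.0295 to 0.118 with single libraries left out. The heat shock list passed with no filter (0.0479), limma-voom (0.0193) and fry (0.0144), and ranged from 0.0205 to 0.165. Fry, which does not compare a list with other genes, also called LPS sensing (0.00224), Fc receptors (0.00151), lipid handling (0.00437), B cell (0.00189), T and NK cell (0.0276), erythroid (0.0254), conventional and plasmacytoid dendritic cell (8.89e-04) and basophil genes (0.0369).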

Other observations

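The tests of gene families, of genes detected at equal depth and of time in culture, and the GC correction, were chosen after the result was seen; the other tests were set before their values were seen. Among 130 families of genes sharing a symbol prefix, camera with its preset correlation called 4. It called the Ccl family higher (8 of 13 higher and 4 lower, median 3.25, adjusted p = 1.01e-04, adjusted p = 0.800 with an estimated correlation and 0.152 with limma-voom). Most of these genes are also in the chemokine list, so this is not a separate result. Ccl22 and Ccl7 had the largest fitted changes. Ccl22 had 0 control reads and only a bound of at least 125-fold, so its rank is not known. Camera also called the Bcl family higher, though only 10 of 21 passed as higher (3 were lower, median 0.35, adjusted p = 0.0214, adjusted p = 0.800 with an estimated correlation and 0.186 with limma-voom). Among them Bcl2a1b, which belongs to a group of survival genes, went from 2.77 ± 0.316 to 214 ± 10.5 CPM (SD, 3 libraries per group), and Bcl2a1c had 0 control reads and was at least 15.3-fold higher; both are near-identical paralogs, so their reads may be split between them.

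Camera called the Parp family lower (0 of 12 higher and 8 lower, median -0.95, adjusted p = 0.0215, adjusted p = 0.800 with an estimated correlation), with Parp12 at -1.78 ± 0.13 and Parp14 at -1.42 ± 0.15. Whether this call is separate from the fall of interferon-stimulated genes was not tested. Over 17 alternatives the adjusted p ran from 5.61e-07 to 0.152 for Ccl, 0.00660 to 0.186 for Bcl and 0.00660 to 0.0370 for Parp; the estimated correlation is not among these 17.

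Neutrophil granule genes were lower in the GM-CSF libraries (S100a8 at 8137 ± 1537 and 3584 ± 471 CPM, control and GM-CSF). A general fall of abundant transcripts, relative to other genes, is argued against. The 100 most abundant other genes had a median log2 fold change of -0.0499, with 43 lower and 37 higher. The 10 most abundant genes of each library did hold a smaller share of counts, 7.60% to 8.07% in GM-CSF against 13.4% to 13.9% in control libraries. A fall limited to the very most abundant transcripts is therefore not argued against. Fewer immature neutrophils among the sorted cells may account for part of the fall of granule genes. In 10 further granule and precursor genes the median was -0.8542, 9 were lower and 0 lay above -0.3. They ran from Padi4 (-1.54 ± 0.09) to Mmp25 (-0.38, adjusted p = 0.159 by edgeR). The labels say that monocytes were sorted, which would remove most neutrophils, and 1 gene of the list stands in another list. A fall of these transcripts within monocytes given GM-CSF stays open and was not tested.

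GM-CSF replicate 3 departed most from the other GM-CSF libraries. Among 8673 genes, 117 lay 2-fold or more from the mean of the rest of its group. GM-CSF replicate 1 had 67 such genes, replicate 2 had 11 and control libraries had 7 to 12, so replicate 1 departed as well. Its log2 deviation correlated with transcript GC content across genes, which are not independent replicates (Spearman correlation 0.3320, against -0.24 to 0.23 in the other libraries), so GC content may account for that trend. It is argued against for the genes that departed 2-fold or more, since 119 did so after the trend was removed and 117 before, 105 of them shared. The correlation with transcript length was -0.1462, which the limits set beforehand left undecided. It lay within the range of the other libraries (-0.17 to 0.25), so it did not set this library apart. At equal depth this library had 13272 genes with a read, against 13822 to 14056 in the others, which is consistent with fewer distinct molecules in it; no biological explanation was tested.

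The number of changed genes, 7511, was reached by 1 of the 10 splits of the 6 samples into 3 and 3, the real one. The highest of the other splits gave 0 with edgeR (11 to 111 genes at an unadjusted p under 0.05). Each of them puts libraries of both groups on either side, which widens the spread within a side, so few calls were bound to result. The 10 splits are also too few for a share under 0.05, so this comparison decides nothing about chance. Whether time in culture contributed cannot be told apart from GM-CSF: 0 libraries form a group of their own that the labels clearly describe as cultured without it.

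Hmox1 was at 196 CPM in GM-CSF replicate 1, at 42.0 and 39.3 CPM in the other GM-CSF libraries and at 142 to 163 CPM in control libraries, and its log2 fold change of -0.70 (edgeR adjusted p = 0.234) was -1.90 and called without that library. Lars2 was at 852 CPM in GM-CSF replicate 3, at 7485 and 6404 CPM in the other GM-CSF libraries and at 9084 ± 260 CPM in control libraries (exact permutation p = 0.1). Rn45s was at 4952 ± 144 CPM in control libraries and at 3790, 3005 and 2785 CPM in GM-CSF libraries (exact permutation p = 0.1), and Mir6236 at 304 ± 45.7 CPM and at 217, 221 and 28.8 CPM (exact permutation p = 0.1).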
